A study of Homo sapiens with 16 samples.

How the data were processed

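Gene expression was measured on 16 Affymetrix arrays of Huh7 cells, 4 for each of untreated, IFNA2 (50 IU/mL), OSM (20 ng/mL) and both cytokines together, after 72 h in 2% serum; doses, times and groups were taken from the labels. The deposited values were 1 intensity per probe set on a linear scale, made by the authors with RMA according to their processing notes, a method that corrects background, quantile normalizes and summarises probes across arrays. The notes do not state the software version. The labels name no batch, scan date or pairing of replicates, so none was modelled. The log2 of each intensity was taken, with no further scaling.

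Of the probe sets 62 were controls; of the others 19064 named 1 gene, 1043 named several and 2108 had no gene in the probe table. Those naming several genes or none were left out. For each of 11963 genes the probe set with the highest mean over all arrays stood for the gene, and 4310 genes had 2 or more to choose from. Genes above a log2 signal of 5 (an intensity of 32) on at least 4 arrays were kept, without regard to group, which left 8319. Probe sets ending in _s_at or _x_at can match several transcripts, and close relatives such as the IFITM, metallothionein, HLA and caspase genes cannot be told apart with certainty on this array. Signal over background limits the precision, and changes of genes near the minimum signal depend on the background correction.

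Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual degrees of freedom, all 16 arrays in 1 fit), and figures were drawn with Python 3.11.15. The comparisons were each treatment against untreated cells, the combination against each single cytokine, OSM against IFNA2, and the interaction, which is the combination's log2 change minus the sum of both single changes. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over the genes of a comparison). On simulated data with these settings, 76.1% of 1.5-fold, 97% of 2-fold and 100% of 4-fold changes were recovered for IFNA2 against untreated, and 53.1%, 90.6% and 95.4% for the interaction, where 28 genes without a change were called. The simulated noise was independent between genes, while 64.9% of the within-group variance of the real arrays lay on 1 axis, so these rates may not hold here. The 28 came beside many simulated genes with a true interaction, so they are no rate for the real calls.

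Of 29 gene lists fixed before the data were examined, 28 had at least 5 measured genes and were tested with limma's camera (preset correlation 0.01, adjusted over the lists of a comparison); MHC class II had fewer and was not tested. Beside the number of members called among all genes, the number after adjusting over the list's members alone is given. The genes named were fixed by a rule: the 8 largest rises and 8 largest falls against untreated cells among called genes whose arrays separated fully, the 6 largest values each way for the combination against each cytokine and for the interaction, up to 4 called and 2 uncalled members of a list, and always the receptors and main signalling genes of both cytokines. Not every gene the rule allows is named, and other genes are said to have been chosen after their values were seen. Of the always-named genes LIFR was on the array but under the minimum signal, so it was not tested, and 1 further gene is not reported here.

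Alternatives covered no filter and a filter at log2 7, quantile normalization, a shift of each array to the same median, the mean of a gene's probe sets, its most variable probe set, no _s_at or _x_at probe sets, an intensity trend with a robust prior, array weights, only the arrays compared, the replicate number as a block, a 2-fold minimum, limma's treat against 1.2-fold, an adjusted p under 0.01, each array left out in turn, an estimated correlation or fry for the lists, and a linear scale for the interaction with 100000 permutations. Added after seeing the data were 3 covariates from each array's own control probe sets: Alu, poly-A spike-ins and the 3' to 5' beta-actin ratio. The tie that shared untreated arrays create between the IFNA2 and OSM changes was measured with 1000 simulated draws of unchanged groups and with the untreated arrays divided in all 6 ways. Chance was tested by regrouping arrays (every other split of a comparison's 8 arrays, or 100 draws). Added after seeing the data were the genes with fully separated arrays in each split and, for the interaction, 100 draws that permuted the residuals of a fit without it.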

Results

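Expression was measured in Huh7 cells, an established human hepatoma line that keeps many traits of hepatocytes. Cells were kept for 72 h in medium with 2% serum, either untreated, with IFNA2 (interferon alpha 2) at 50 IU/mL, with OSM (oncostatin M, a cytokine of the interleukin 6 family) at 20 ng/mL, or with both. Each of these 4 groups had 4 arrays. An array gave 1 intensity per probe set; intensities ran from 5.87 to 22200, and the median intensity of an array lay between 61.7 and 65. The number of arrays limits the precision of every value below. The design addresses what each cytokine changed alone, and whether the combination differed from each of them. A change is given as the log2 difference between group means ± its SE in the fit, with 4 arrays per group, and a level as the mean log2 intensity ± SD over the 4 arrays of a group. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples. Among genes named below, beside those for which it is said, untreated levels lay under the minimum log2 signal of 5 for IFIH1, RIGI, MT1M, PSMB9, IFITM1, TDO2, SOCS2, SOCS3, CD44, CLDN4, SPP1, IL15, SPARC, CD3D and IFNAR1, and background sets the size of their changes as well.

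The comparison of IFNA2 with untreated cells shows what interferon changed alone. Antiviral genes made the largest changes. MX1, which encodes a GTPase that restricts many viruses, rose by 6.87 ± 0.12 (adjusted p = 1.5e-15), from a level of 4.63 ± 0.3 to 11.5 ± 0.12. IFIT1, which binds viral RNA, rose by 5.97 ± 0.11, IFI6 by 5.96 ± 0.14 and the ubiquitin-like modifier ISG15 by 4.29 ± 0.1. The RNA-sensing synthetases OAS1 and OAS3 rose by 4.17 ± 0.17 and 3.53 ± 0.1. The untreated levels of MX1, IFIT1 (3.98 ± 0.2) and OAS1 (4.9 ± 0.24) lay under the minimum log2 signal of 5, where background sets the size of a ratio. On the arrays, 33 of the 35 measured antiviral interferon-stimulated genes rose and none fell (34 adjusted over the list alone; camera adjusted p = 1.5e-45). The 2 not called were MX2, with a change of 0.2 ± 0.06 (adjusted p = 0.052), and TRIM5, with 0.03 ± 0.1 (adjusted p = 0.85); both were chosen after their values were seen.

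Interferon signalling and sensing genes rose beside them. Of 12 measured genes of the interferon receptor and signalling list, 4 rose (5 adjusted over the list alone; camera adjusted p = 0.0039, and adjusted p = 0.051 with an estimated correlation). These were IRF9, the DNA-binding part of the interferon-activated complex (4 ± 0.12), USP18, which restrains the interferon receptor (2.75 ± 0.12), the transcription factor IRF1 (0.76 ± 0.12) and the feedback inhibitor SOCS1 (0.58 ± 0.12). The receptor chains IFNAR1 and IFNAR2 were not called, with changes of -0.08 ± 0.28 and -0.04 ± 0.09. Among 10 genes of viral RNA and DNA sensing 5 rose (6 adjusted over the list alone, and 1 lower; camera adjusted p = 0.0048): IFIH1 by 3.37 ± 0.19, RIGI by 1.89 ± 0.24, the adaptor MYD88 by 0.58 ± 0.08, TICAM1 by 0.49 ± 0.12 and IKBKE by 0.45 ± 0.1, the last 3 chosen after their values were seen. The call of TICAM1 was lost without untreated replicate 3 (adjusted p = 0.067) and without IFNA2 replicate 2 (adjusted p = 0.063). Antigen presentation rose too: 15 of 18 genes of MHC class I and antigen processing were higher (15 adjusted over the list alone; camera adjusted p = 1.4e-11). The peptide transporter TAP1 rose by 1.72 ± 0.13, the immunoproteasome subunits PSMB9 and PSMB8 by 1.6 ± 0.12 and 1.56 ± 0.15, and HLA-B by 1.02 ± 0.12, the last on an _x_at probe set that can match other HLA transcripts.

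Smaller rises reached genes of the liver's inflammatory response. Of 18 acute phase genes 8 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0075, and adjusted p = 0.2 with an estimated correlation). LBP, which carries bacterial lipopolysaccharide, rose by 1.31 ± 0.09, the iron-binding LCN2 by 0.98 ± 0.09, the protease inhibitor SERPINA3 by 0.95 ± 0.1 and haptoglobin (HP, whose probe set can match HPR) by 0.87 ± 0.11. The 2 that fell, chosen after their values were seen, were the fibrinogen chains FGB (-0.39 ± 0.1) and FGG (-0.32 ± 0.1); FGB was not called with 1 of 5 single arrays left out (adjusted p up to 0.095), nor FGG with 1 of 9 (adjusted p up to 0.15). Of 20 complement genes 9 rose (12 adjusted over the list alone, and 1 lower; camera adjusted p = 0.0048, and adjusted p = 0.14 with an estimated correlation), among them CFB by 1.11 ± 0.12, C1R by 0.9 ± 0.11 and C1S by 0.79 ± 0.06. Of 17 genes of iron, zinc and metal handling 10 rose (11 adjusted over the list alone; camera adjusted p = 0.00017, and adjusted p = 0.14 with an estimated correlation), led by the metallothioneins MT1M (1.43 ± 0.14) and MT2A (0.87 ± 0.1), whose family members are near identical. Chemokines and cytokines rose in 8 of 17 cases (9 adjusted over the list alone; camera adjusted p = 0.0039), with CXCL10, which draws T cells, up by 0.93 ± 0.09 and IL32 by 0.66 ± 0.12. The NF-kB list rose in 8 of 12 genes (11 adjusted over the list alone; camera adjusted p = 7.4e-05, and adjusted p = 0.18 with an estimated correlation), led by the adhesion molecule ICAM1 (0.61 ± 0.07). The STAT3 pathway list rose in 8 of 20 (10 adjusted over the list alone, and 1 lower; camera adjusted p = 0.024, and adjusted p = 0.066 with an estimated correlation), with STAT3 up by 0.55 ± 0.11. Of 32 cell cycle genes 5 fell and none rose by limma (7 and 2 adjusted over the list alone; camera adjusted p = 0.31), with a median change over the 32 of 0.03 and a mean of -0.12. These 5 were the mitotic motor KIF11 (-1.28 ± 0.4), CENPF (-1.06 ± 0.31), the cyclin CCNE2 (-0.43 ± 0.14), CDK1 (-0.38 ± 0.09) and TTK (-0.37 ± 0.09), the last chosen after its values were seen. With the Alu control of each array as a covariate, chosen after the data were seen, TTK alone of them was called. With single arrays left out, CCNE2 was not called in 11 cases (adjusted p up to 0.16), KIF11 in 9 (up to 0.13), CENPF in 6 (up to 0.13) and TTK in 3 (up to 0.085).

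Of 8319 genes tested, 985 were higher and 340 lower with IFNA2; 40 and 31 of these changed at least 2-fold. The excess of rises depended on the scaling: with arrays shifted to 1 median 505 were higher and 433 lower, and with quantile normalization 621 and 396. All 4 arrays of a group lay beyond all 4 of the other for 1834 of the 8319 genes, called or not. A mixed grouping of the same arrays separated more genes, 2860, so the 1834 do not argue against chance. The largest falls included the RNA surveillance factor SKIC3 (-1.28 ± 0.28, adjusted p = 0.01) and the decoy death receptor TNFRSF10D (-1.19 ± 0.21, adjusted p = 0.0022). PIK3C2A (-1.21 ± 0.25) and JMJD1C (-1.2 ± 0.27) fell as well, but were not called with the Alu control of each array as a covariate, chosen after the data were seen. With it 276 genes were higher and 55 lower. The log2 signal of that control was 14.06 ± 0.1 in untreated cells, 13.89 ± 0.09 with IFNA2, 13.91 ± 0.15 with OSM and 13.94 ± 0.11 with both. Leaving out single arrays moved the higher count to between 292 (without untreated replicate 3) and 1690 (without IFNA2+OSM replicate 3), by over 1.5 times also without untreated replicates 2 and 4 or any IFNA2 replicate. The lower count went from 43 (without untreated replicate 3) to 939 (without IFNA2 replicate 1), and moved as far without the other untreated or IFNA2 replicates or IFNA2+OSM replicates 1, 2 and 3.

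**Figure D1:**
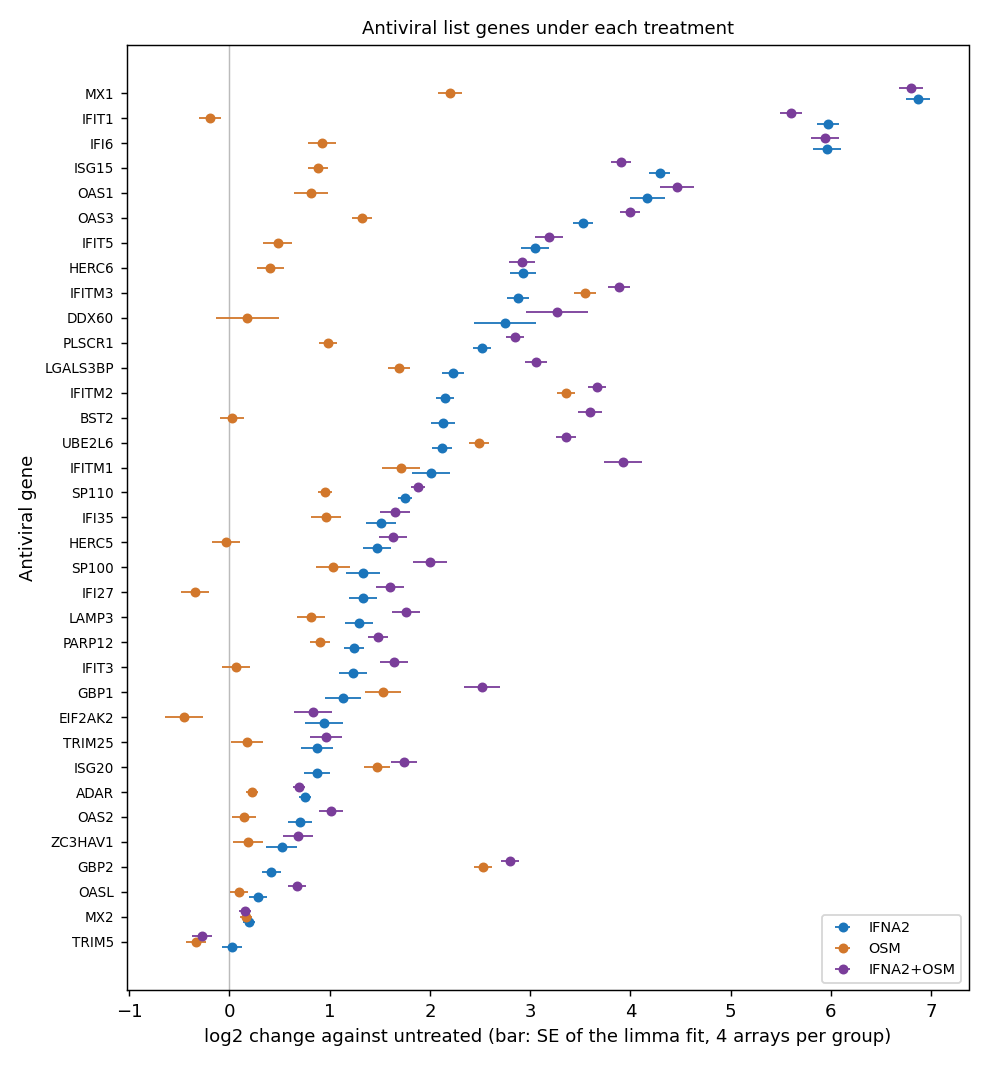
Log2 change against untreated cells (x axis) of each of the 35 measured antiviral genes (y axis) with IFNA2, OSM or both; points are differences of group means and bars their SE, with 4 arrays per group. MX1 lay at 6.87 with IFNA2, 2.2 with OSM and 6.8 with both.

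The comparison of OSM with untreated cells shows what oncostatin M changed alone, and the response was that of an acute phase liver. All 18 measured positive acute phase genes rose (18 adjusted over the list alone; camera adjusted p = 9.2e-21). LBP rose by 6.84 ± 0.09 (adjusted p = 8.8e-18), from a level of 5.54 ± 0.1 to 12.38 ± 0.06. SERPINA3 rose by 5.4 ± 0.1, the iron-regulating hormone HAMP by 4.99 ± 0.12, CRP by 4.85 ± 0.13 and HP by 4.77 ± 0.11. Of 20 complement genes 18 rose and 1 fell (18 and 2 adjusted over the list alone; camera adjusted p = 1.2e-13), with C1R up by 4.92 ± 0.11, C8B by 4.05 ± 0.18 and CFB by 3.87 ± 0.12; the 1 that fell was MASP1, a protease of the lectin pathway (-1.13 ± 0.09, chosen after its values were seen). The secreted phospholipase PLA2G2A rose by 7.92 ± 0.23 and NNMT, which methylates nicotinamide, by 7.9 ± 0.13. REG3A and REG1A, secreted proteins of the gut and pancreas, rose by 6.72 ± 0.13 and 5.79 ± 0.14, and the protease inhibitor TIMP1 by 5.29 ± 0.21. The untreated levels of PLA2G2A (4.6 ± 0.51), NNMT (4.69 ± 0.16), REG3A (3.46 ± 0.21), REG1A (4.44 ± 0.17) and CRP (3.47 ± 0.12) lay under log2 5, so the sizes and the order of these rises depend on background. The largest fall was in NT5E, which makes adenosine (-1.94 ± 0.17). BEX1 changed by -1.87 ± 0.1, the nuclear receptor NR4A2 by -1.74 ± 0.11, the chromatin protein HMGA2 by -1.69 ± 0.16 and the matrix protein CCN2 by -1.67 ± 0.09.

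The receptor of OSM and its feedback genes rose with it. In the STAT3 pathway list 14 of 20 genes rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 1.1e-07). The feedback inhibitor SOCS3 rose by 2.9 ± 0.11, the transcription factors JUNB and CEBPD by 2.45 ± 0.08 and 2.44 ± 0.08, the receptor chain OSMR by 2.3 ± 0.19 and STAT3 itself by 1.94 ± 0.11; MYC, which drives growth, was the 1 that fell (-1.01 ± 0.11, chosen after its values were seen). The shared receptor chain IL6ST was not called (0.55 ± 0.24, adjusted p = 0.079). Metal handling genes rose in 12 of 17 cases (12 adjusted over the list alone; camera adjusted p = 1.4e-08), among them MT1M by 3.63 ± 0.14 and the haem-degrading enzyme HMOX1 by 2.11 ± 0.13. Cytokine receptors and co-stimulation genes rose in 13 of 17 (13 adjusted over the list alone; camera adjusted p = 2.2e-06), with IL1R1 up by 2.85 ± 0.13 and IL4R by 1.83 ± 0.09. Of 17 chemokines and cytokines 8 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0062). CXCL2 rose by 2.09 ± 0.11, on a probe set that can match CXCL3, IL32 by 2.07 ± 0.12 and IL15, a growth factor of lymphocytes, by 1.81 ± 0.13. The 2 that fell, chosen after their values were seen, were CX3CL1 (-0.59 ± 0.11) and CXCL10 (-0.3 ± 0.09). NF-kB genes rose in 8 of 12 cases (9 adjusted over the list alone; camera adjusted p = 0.0015, and adjusted p = 0.21 with an estimated correlation).

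Genes of cell division went the other way: 27 of 32 cell cycle and DNA replication genes fell and none rose (28 adjusted over the list alone; camera adjusted p = 3.6e-10). The mitotic kinase CDK1 fell (-0.97 ± 0.09, adjusted p = 1.8e-07), from 10.84 ± 0.17 to 9.87 ± 0.1. TOP2A, which untangles DNA, changed by -1.27 ± 0.37, and its call was lost without untreated replicate 3 (adjusted p = 0.051). Of 12 genes of arrest and p53 targets 6 rose (6 adjusted over the list alone; camera adjusted p = 0.02), including the stress gene GADD45B (2.11 ± 0.09) and the cyclin-dependent kinase inhibitor CDKN1A (1.44 ± 0.11). Hypoxia and glycolysis genes rose in 17 of 21 cases (18 adjusted over the list alone; camera adjusted p = 6.6e-10), with hexokinase HK2 up by 2.05 ± 0.09, the peptide hormone ADM by 1.82 ± 0.08 and the aldolase ALDOC by 1.62 ± 0.13. Genes of the unfolded protein and amino acid response rose in 11 of 19 (12 adjusted over the list alone; camera adjusted p = 0.0024, and adjusted p = 0.051 with an estimated correlation), with DDIT4 up by 1.93 ± 0.13. Of 18 apoptosis genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.016): the inflammatory caspases CASP4 and CASP1 rose by 1.66 ± 0.06 and 1.62 ± 0.14, on probe sets that can match related caspases, and DAPK1, chosen after its values were seen, fell (-0.21 ± 0.06). Of 21 epithelial and mesenchymal genes 8 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.016). The hyaluronan receptor CD44 rose by 3.88 ± 0.11 and the tight junction protein CLDN4 by 1.6 ± 0.16. The 2 that fell, chosen after their values were seen, were ITGB1 (-0.46 ± 0.15) and CDH2 (-0.3 ± 0.09); ITGB1 was not called without OSM replicate 2 or 3 or untreated replicate 3 or 4 (adjusted p up to 0.083), nor CDH2 without OSM replicate 2 or 3 (adjusted p up to 0.059).

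OSM alone also raised antiviral and antigen presentation genes. Of 35 antiviral genes 23 rose and 1 fell (23 and 3 adjusted over the list alone; camera adjusted p = 1.8e-08). IFITM3 and IFITM2, which block virus entry and whose probe sets can match each other, rose by 3.55 ± 0.11 and 3.36 ± 0.09. The interferon-inducible GTPase GBP2 rose by 2.53 ± 0.09, the ISG15-conjugating enzyme UBE2L6 by 2.49 ± 0.1 and MX1 by 2.2 ± 0.12. IFIT1 (-0.19 ± 0.11), BST2, which tethers virus particles (0.03 ± 0.12), and USP18 (-0.03 ± 0.12) were not called; their levels without IFNA2 were under log2 5 for the first 2. The 1 that fell was TRIM5 (-0.33 ± 0.1, chosen after its values were seen), not called with the Alu covariate. In the interferon signalling list 6 of 12 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0083), with SOCS1 up by 2.85 ± 0.12, IRF9 by 1.9 ± 0.12 and IRF1 by 1.44 ± 0.12. The 1 that fell, chosen after its values were seen, was PIAS1 (-0.52 ± 0.19), whose call was lost with untreated replicate 2, 3 or 4, OSM replicate 2 or 3, or IFNA2 replicate 3 or 4 left out (adjusted p of 0.051 to 0.13). Of 18 MHC class I genes 15 rose (16 adjusted over the list alone; camera adjusted p = 9.5e-09), with PSMB9 up by 2.12 ± 0.12, PSMB8 by 2.1 ± 0.15 and the peptide-loading protein TAPBP by 1.72 ± 0.11.

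With OSM 1962 of 8319 genes were higher and 1545 lower, 355 and 107 of them at least 2-fold. Which direction was more frequent depended on the scaling: with arrays shifted to 1 median 1524 were higher and 2034 lower, and with quantile normalization 1716 and 1712. Arrays of the groups separated fully for 3162 of the 8319 genes, called or not. The signal of OSM replicate 1 differed in 3' to 5' ratios of control probe sets. Its log2 ratio of the 3' to the 5' beta-actin probe sets was 0.791, with 0.085 to 0.227 on the 15 other arrays. Of the poly-A spike-ins, dap had 1.827 (0.737 to 1.162 on the others) and thr 2.234 (1.099 to 1.701 on the others). Spike-ins are not RNA of the cells, so the ratios of that array cannot be read as RNA integrity of its cells alone. Without that array 1791 genes were higher and 1516 lower.

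**Figure D2:**
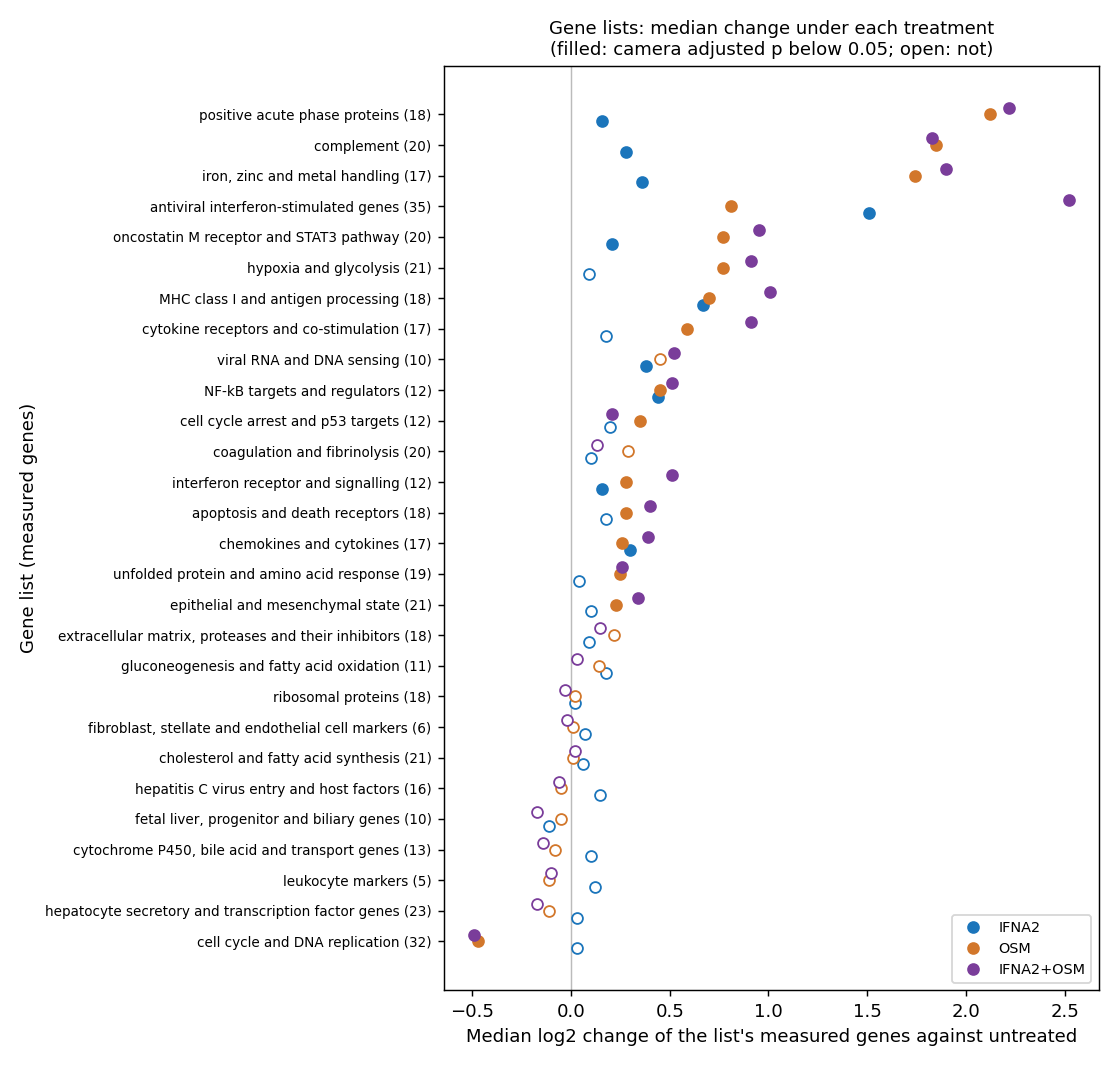
Median log2 change against untreated cells (x axis) of the measured genes of each of 28 gene lists (y axis, with the number of genes) with IFNA2, OSM or both; filled points passed the list test. The acute phase list had a median of 0.16 with IFNA2, 2.12 with OSM and 2.22 with both.

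The direct comparison of OSM with IFNA2 does not rest on the untreated means. The acute phase and antiviral genes parted in it: all 18 acute phase genes were higher with OSM (18 adjusted over the list alone; camera adjusted p = 1.8e-28), and 24 of 35 antiviral genes were lower (25 adjusted over the list alone; camera adjusted p = 5.8e-11). IFIT1 was lower by -6.16 ± 0.11, IFI6 by -5.05 ± 0.14 and MX1 by -4.67 ± 0.12. The 5 antiviral genes higher with OSM (6 adjusted over the list alone) were GBP2 (2.11 ± 0.09), IFITM2 (1.21 ± 0.09), IFITM3 (0.67 ± 0.11), the exonuclease ISG20 (0.6 ± 0.13) and UBE2L6 (0.37 ± 0.1), ISG20 being chosen after its values were seen. Of 18 MHC class I genes 7 were higher with OSM and none lower (7 adjusted over the list alone; camera adjusted p = 0.063). In all, 1059 genes were higher with OSM than with IFNA2 and 1239 lower; of those changed at least 2-fold more were higher, 254 against 104.

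Many genes moved the same way under both cytokines. Among the genes called higher, 625 were shared by IFNA2 and OSM, where independent calls would share 232; among those called lower, 229 were shared, where 63.1 would be. Both comparisons use the same untreated arrays, which alone ties them. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.495, against 0.459 on average and up to 0.923 (95th percentile) for simulated unchanged groups that share their controls. Their covariance was 0.1033, against 0.0094 in the simulation, and 0.0972 when the untreated arrays were divided between the comparisons.

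The comparison of the combination with untreated cells shows whether both responses appeared together, and they did. Against untreated cells, 33 of 35 antiviral genes rose and 1 fell (34 and 1 adjusted over the list alone; camera adjusted p = 7.3e-29), and all 18 acute phase genes rose (18 adjusted over the list alone; camera adjusted p = 1.6e-20). MX1 rose by 6.8 ± 0.12, IFI6 by 5.94 ± 0.14 and IFIT1 by 5.6 ± 0.11, beside PLA2G2A by 8.06 ± 0.23, NNMT by 8.02 ± 0.13, REG3A by 7.11 ± 0.13 and LBP by 6.97 ± 0.09. The antiviral gene that fell, chosen after its values were seen, was TRIM5 (-0.27 ± 0.1), not called without untreated replicate 2 or 3 or IFNA2+OSM replicate 1, 3 or 4 (adjusted p up to 0.11). Of 18 MHC class I genes 16 rose (17 adjusted over the list alone; camera adjusted p = 4.3e-12), and of 32 cell cycle genes 26 fell (29 adjusted over the list alone; camera adjusted p = 1.9e-09). The actin-binding protein TAGLN (-2.15 ± 0.2), BEX1 (-2 ± 0.1), NT5E (-1.9 ± 0.17) and type II collagen COL2A1 (-1.89 ± 0.08) fell most, with GSTA1 (-2.05 ± 0.16), whose paralogs are near identical. In all 1818 genes were higher and 1674 lower, 409 and 105 of them at least 2-fold. More were lower than higher with arrays shifted to 1 median (1515 higher and 2117 lower) and with quantile normalization (1625 and 1923). Arrays separated fully for 3362 of the 8319 genes, called or not.

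Against IFNA2 alone, which shows what OSM added to interferon, the combination raised all 18 acute phase genes (18 adjusted over the list alone; camera adjusted p = 2.3e-27) and 14 of 20 STAT3 pathway genes, with MYC lower by -0.77 ± 0.11 (16 and 1 adjusted over the list alone; camera adjusted p = 5.5e-10). SOCS3 was higher by 2.93 ± 0.11 and OSMR by 2.34 ± 0.19. Antiviral genes rose in 15 of 35 cases and fell in 3 (17 and 3 adjusted over the list alone; camera adjusted p = 4e-06). GBP2 was higher by 2.37 ± 0.09, IFITM1 by 1.92 ± 0.19 and BST2 by 1.47 ± 0.12. The 3 that fell, chosen after their values were seen, were ISG15 (-0.39 ± 0.1), IFIT1 (-0.38 ± 0.11), not called without IFNA2 replicate 3 (adjusted p = 0.053), and TRIM5 (-0.3 ± 0.1), not called without IFNA2 replicate 3 or 4 or IFNA2+OSM replicate 3 or 4 (adjusted p up to 0.11). MX1 (-0.07 ± 0.12) and USP18 (-0.19 ± 0.12) were not called. In MHC class I 13 of 18 genes rose (13 adjusted over the list alone; camera adjusted p = 1e-08), with PSMB9 higher by 1.9 ± 0.12 and TAP1 by 1.12 ± 0.13. In all 1101 genes were higher and 1496 lower; of those changed at least 2-fold more were higher, 285 against 83.

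Against OSM alone, which shows what interferon added to OSM, 142 genes changed, and antiviral genes made the largest rises. Of 35 antiviral genes 28 rose (32 adjusted over the list alone; camera adjusted p = 7.6e-106): IFIT1 by 5.79 ± 0.11, IFI6 by 5.02 ± 0.14, MX1 by 4.6 ± 0.12 and BST2 by 3.57 ± 0.12. MHC class I genes rose in 8 of 18 cases (12 adjusted over the list alone; camera adjusted p = 2.5e-17), with PSMB9 up by 1.37 ± 0.12 and TAP1 by 1.23 ± 0.13. The 2 signalling genes that rose of 12 were USP18 (2.6 ± 0.12) and IRF9 (2.01 ± 0.12; 2 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.086 with an estimated correlation). Both sensing genes that rose of 10 were the RNA helicases IFIH1 (2.86 ± 0.19) and RIGI (2.06 ± 0.24; 2 adjusted over the list alone; camera adjusted p = 0.00059). No acute phase gene was called, with 1 higher when adjusted over the list alone (limma; camera adjusted p = 0.76). In all 96 genes were higher and 46 lower, and 29 and 1 of these changed at least 2-fold. SLC2A2, the main glucose carrier of hepatocytes, was the 1 that fell (-1.36 ± 0.12, adjusted p = 3.8e-06). Its level in the combination (4.18 ± 0.2) lay under log2 5, where background sets the size of a fall. More genes were lower than higher with the poly-A spike-in controls as a covariate, chosen after the data were seen (244 higher and 328 lower), and with array weights (1738 and 1906). Leaving out single arrays gave 24 lower genes (without OSM replicate 2) to 78 (without OSM replicate 4), and moved that count by over 1.5 times also without OSM replicate 3 or IFNA2+OSM replicate 1, 2 or 4.

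Genes whose level was highest in the combination, above untreated cells and above each cytokine alone, numbered 47. They included the antigen presentation genes PSMB9 (8.32 ± 0.17, against 6.42 ± 0.24 with IFNA2 and 6.95 ± 0.11 with OSM), TAP1 (8.03 ± 0.18, against 6.92 ± 0.14 and 6.8 ± 0.15) and HLA-B (8.8 ± 0.22, against 7.89 ± 0.19 and 7.75 ± 0.16). The antiviral genes IFITM1 (8.82 ± 0.28, against 6.9 ± 0.17 and 6.59 ± 0.34), BST2 (8.21 ± 0.11, against 6.74 ± 0.08 and 4.64 ± 0.26) and UBE2L6 (12.1 ± 0.11, against 10.87 ± 0.12 and 11.23 ± 0.15) did so as well. TDO2, which degrades tryptophan, lay at 6.22 ± 0.1, against 4.31 ± 0.43 and 5.02 ± 0.18. Genes lowest in the combination numbered 30, among them SLC2A2 (4.18 ± 0.2, against 5.07 ± 0.19 and 5.55 ± 0.1) and COL2A1 (10.59 ± 0.1, against 12.67 ± 0.05 and 11.03 ± 0.17). Leaving out single arrays gave 16 (without IFNA2+OSM replicate 1) to 46 (without OSM replicate 4) genes lowest in the combination, over 1.5 times away also without OSM replicate 2 or 3 or IFNA2+OSM replicate 2 or 4. Both counts depended on the fit: genes highest and lowest in the combination numbered 24 and 8 in fits of only the arrays compared, 94 and 76 with the Alu covariate, 131 and 171 with the poly-A covariate and 412 and 640 with array weights.

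**Figure D3:**
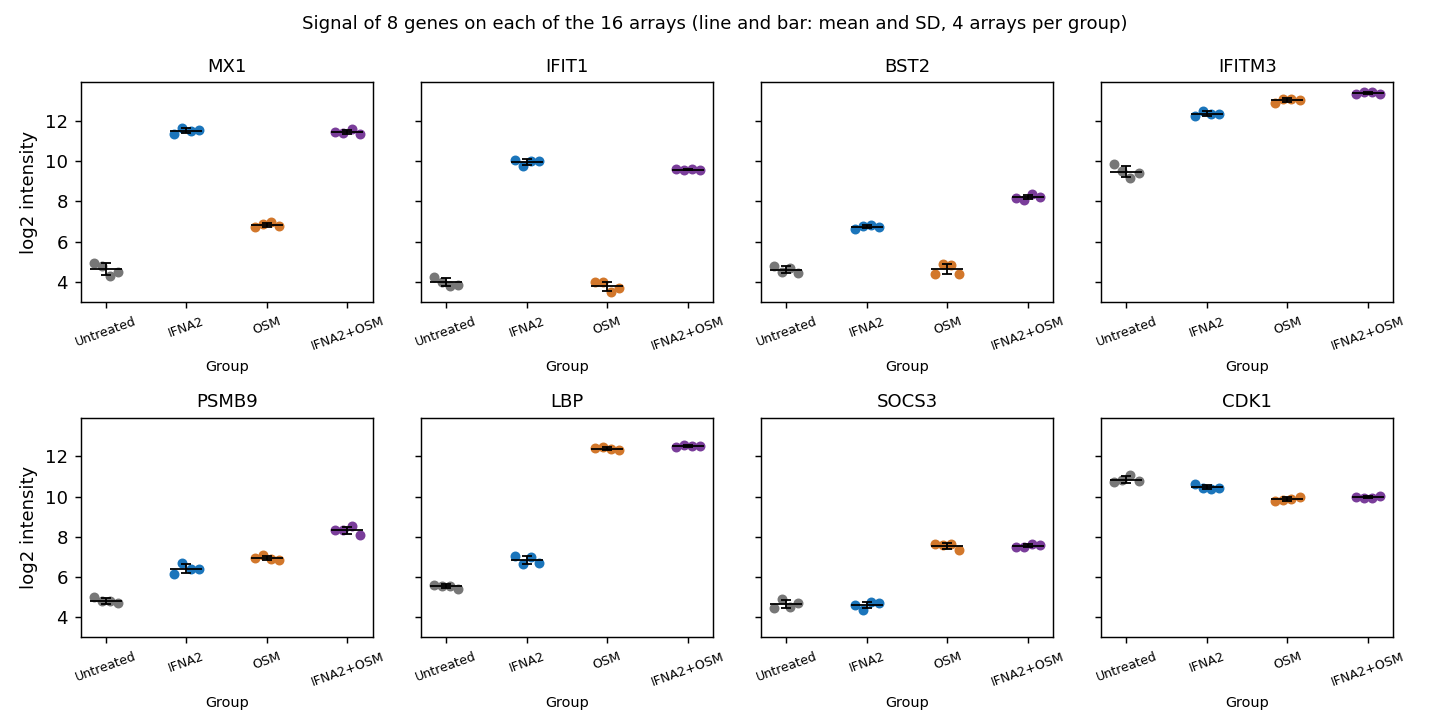
Log2 intensity (y axis) of 8 genes on each of the 16 arrays by group (x axis); lines and bars are the mean and SD of 4 arrays. BST2 and PSMB9 lay highest in the combination, at 8.21 and 8.32, and IFIT1 lay at 3.98 in untreated cells and at 3.79 with OSM.

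The interaction asks whether the log2 change with both cytokines departs from the sum of their single changes. Several genes that each cytokine raised alone fell short of that sum. IFITM3 lay -2.54 ± 0.16 from it (adjusted p = 3.9e-07), MX1 -2.27 ± 0.17 (adjusted p = 1.8e-06), IRF9 -1.99 ± 0.17 and IFITM2 -1.83 ± 0.13. BST2 lay above the sum, by 1.44 ± 0.16 (adjusted p = 0.0002); its levels without IFNA2 lay under log2 5. Of 35 antiviral genes 11 were below the sum and 1 (BST2) above (14 and 2 adjusted over the list alone; camera adjusted p = 0.001, and adjusted p = 0.19 with an estimated correlation). The acute phase list had 4 of 18 below (8 adjusted over the list alone, and 1 above; camera adjusted p = 0.019, and adjusted p = 0.45 with an estimated correlation): LBP (-1.18 ± 0.12), SERPINA3 (-0.9 ± 0.15), HP (-0.9 ± 0.16) and LCN2 (-0.64 ± 0.13), the last not called with 1 of 10 single arrays left out (adjusted p up to 0.084). The metal list had 2 of 17 below (9 adjusted over the list alone; camera adjusted p = 0.007, and adjusted p = 0.45 with an estimated correlation): MT1M (-1.2 ± 0.2) and MT2A (-0.67 ± 0.15), the last not called with 1 of 12 single arrays left out (adjusted p up to 0.12). The peptide-loading protein TAPBP was the 1 of 18 MHC class I genes below the sum (-0.88 ± 0.16; 6 adjusted over the list alone; camera adjusted p = 0.045, and adjusted p = 0.53 with an estimated correlation). The complement list had 2 of 20 below (10 adjusted over the list alone, and 1 above; camera adjusted p = 0.039, and adjusted p = 0.45 with an estimated correlation): CFB (-0.87 ± 0.17) and C1S (-0.43 ± 0.09), not called with 1 of 10 and 1 of 8 single arrays left out (adjusted p up to 0.075 and 0.088). Of 20 coagulation genes 2 were below (7 adjusted over the list alone; camera adjusted p = 0.039, and adjusted p = 0.53 with an estimated correlation): plasminogen, PLG (-0.77 ± 0.12), and its inhibitor SERPINF2 (-0.64 ± 0.13), the last not called with 1 of 12 single arrays left out (adjusted p up to 0.1). No gene of 12 on the NF-kB list was called (2 below adjusted over the list alone; camera adjusted p = 0.048, and adjusted p = 0.56 with an estimated correlation). Outside these lists, the heat shock cochaperone CHORDC1 (0.65 ± 0.11) and the gut peptide NTS (0.78 ± 0.14) lay above the sum. On the linear scale, where the combination is set against the sum of both changes in intensity, none of the 4 acute phase genes lay below the sum by a test that passed: LBP turned to lie above it (417, adjusted p = 0.029), SERPINA3 (32.2) and LCN2 (176) turned without passing, and HP did not pass (-470, adjusted p = 0.1). Of the complement genes C1S turned and passed (582, adjusted p = 0.0011) and CFB turned without passing (135). MT1M turned as well (3.58), and MX1, IFITM2 and MT2A kept their direction without passing (adjusted p = 0.2, 0.11 and 0.51), while the other genes named in this paragraph passed in the direction given.

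In all 11 genes lay above the sum and 50 below (22 and 35 with arrays shifted to 1 median). These counts rested on single arrays: the first ran from 4 (without untreated replicate 2) to 836 (without IFNA2+OSM replicate 3), and the second from 24 (without OSM replicate 3) to 1491 (without IFNA2+OSM replicate 3). Leaving out any array other than OSM replicate 1 moved the first by over 1.5 times, and any other than OSM replicate 1 or IFNA2 replicate 2 the second.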

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

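Of the tests in this part, those with the Alu control were set out before their results were seen; the tests of mixed RNA, of a smaller interferon-type response, of the linear scale and of a signal ceiling, also for its 8 genes and ISG15, were chosen after. Antiviral genes rose with OSM alone, 23 of 35, and 24 of the 35 were lower with OSM than with IFNA2. RNA of IFNA2-treated cells in the OSM samples is argued against as the cause for the list as a whole, since it needs 1 share of the IFNA2 signal in all genes: the share that fitted the most of the 23 within 2 SE (51.3%) fitted 7. A smaller interferon-type response in the OSM cultures stays open for the list as a whole, since the Spearman rho of both changes was 0.3 (35 genes, permutation p = 0.077), which leaves the ranking of genes undecided. For 5 of the 35 it is argued against, as GBP2, IFITM2, IFITM3, ISG20 and UBE2L6 were higher with OSM than with IFNA2; that bound was set with the count known. A direct response of these 5 genes to OSM may be a hypothesis to test, with this value of 5 from the same data it was found in.

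IFNA2 lowered 340 genes, with a median change of -0.55 (median SE 0.15). With the Alu control of each array as a covariate the median was -0.34 (median SE 0.13) and 39 of them were still called; the SE was smaller, so the calls ended with the smaller changes. Of the 340, 312 correlated positively with that control within groups (median r 0.69, against -0.61 for the raised genes and -0.19 for genes not called). The raised genes went from a median of 0.4 to 0.27, with 254 still called. Since the control also differed between groups, RNA and labelling differences between arrays cannot be told apart from an effect of IFNA2 for the lowered genes. The same holds for the raised genes as a group, of which 254 of 985 were still called, although no bound was set for them beforehand.

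The combination lay below the sum of both log2 effects for 50 genes. On the linear scale 30 of the 50 had a negative interaction that passed its permutation test, 5 had a positive one that passed and 15 had none that passed. The 50 were chosen for a negative log2 interaction on these same arrays. For genes that 1 cytokine left unchanged, both scales also give the same sign. These counts therefore cannot decide for the group whether the response adds up on the linear scale, and that stays open for the 15. A signal ceiling common to the array is argued against for the 42 genes whose sum lay under the 99th percentile of log2 signals (12.99), with a median of -0.68. Lower ceilings of single probe sets were not tested for these 42. For ISG15 a ceiling is argued against, as its combination lay below the level of the same probe set with IFNA2 alone (12.32 against 12.7, -0.39 ± 0.1). A ceiling stays open for the other 7 (IFITM3, MX1, IFITM2, UBE2L6, LBP, HP and CEBPD), which hold 5 of the 8 most negative interactions: for 2 the sum exceeded the highest signal (14.44), and for 2 the combination itself lay above 12.99. RNA and labelling differences that the Alu control follows are argued against as the whole cause. With that covariate the median interaction went from -0.78 to -0.67 (median SE 0.13 in both) and 38 of the 50 were still called. The 50 were picked by their interaction, and differences that this 1 control does not follow are not covered. Saturation of shared signalling may be a biological explanation, and the -0.67 does not test it.

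In 34 of 532 groups of 4 arrays, 1 array of a named gene lay apart, with a gap to its nearest neighbour, as a share of the group's range, beyond Dixon's 95% limit; chance alone marks about 1 in 20 groups. The share of the range and the side are given: IFNA2+OSM replicate 3 for COL2A1 (0.988, high), ELOVL6 (0.948, low), HMGA2 (0.86, low), ISG20 (0.848, high), ITGB1 (0.87, low), NSDHL (0.858, high), NT5E (0.905, low), PIAS1 (0.853, low), SERPINF2 (0.855, high), SKIC3 (0.855, low) and USP18 (0.903, high), and IFNA2 replicate 1 for CXCL10 (0.848, high), HLA-B (0.85, low), IL15 (0.845, high), IL6ST (0.932, high), KIF11 (0.902, high), OAS3 (0.881, low), PIK3C2A (0.892, high), PSMB8 (0.83, low), SC5D (0.835, high) and SKIC3 (0.95, high). Others were OSM replicate 4 for BEX1 (0.853, low), CRP (0.839, low) and SOCS3 (0.871, low), untreated replicate 1 for BEX1 (0.872, high), CDH2 (0.881, low) and ISG15 (0.885, high), untreated replicate 4 for C1R (0.868, high), CASP4 (0.906, low) and SPP1 (0.841, low). The rest were OSM replicate 1 for NT5E (0.855, high) and TNFRSF10D (0.924, low), IFNA2 replicate 3 for IFITM1 (0.924, high) and untreated replicate 3 for TICAM1 (0.841, low). IFNA2 replicate 1 held 10 of the 34 and IFNA2+OSM replicate 3 held 11. Of 36 groups of array measures 2 were set apart, both by OSM replicate 1: the 3' to 5' ratio of beta-actin (0.869 of the range; 0.79 against 0.23 for its neighbour on the log2 scale) and of GAPDH (0.917; 0.11 against -0.1).

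The effect of 1 cytokine differed with the other present for 11 genes above and 50 below the sum of the log2 effects. Of the genes named in the text, those below were IFITM3 (-2.54), MX1 (-2.27), IRF9 (-1.99), IFITM2 (-1.83), ISG15 (-1.27), UBE2L6 (-1.25), MT1M (-1.2), LBP (-1.18), IFI6 (-0.94), SERPINA3 (-0.9), HP (-0.9), TAPBP (-0.88). Also below were CFB (-0.87), OAS3 (-0.84), PLG (-0.77), CEBPD (-0.76), MT2A (-0.67), CPT1A (-0.66), LCN2 (-0.64), SERPINF2 (-0.64), COL2A1 (-0.63) and C1S (-0.43). Above were CHORDC1 (0.65), NTS (0.78) and BST2 (1.44). With 1 array left out, IFI6 was not called in 11 cases (adjusted p up to 0.11), COL2A1 in 8 (up to 0.063) and CPT1A in 6 (up to 0.058), beside the genes named as such in the account of the interaction.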

How the results depend on the processing

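The Alu, poly-A and beta-actin covariates were chosen after the data were seen; all other alternatives were planned. Called values of named genes kept their direction and call in 9263 cases over the alternatives other than leaving out an array. They kept the direction without the call in 689 and changed direction in 12. No list test called in the main setting or in the alternative changed direction. Lists called in neither could turn, as the fetal liver list did for OSM with fry. Counts that moved by over 1.5 times are given as higher and lower genes, by comparison (against untreated cells unless said); the cause was not tested, except that stricter thresholds call fewer genes by construction and fewer probe sets leave fewer genes to test. A 2-fold minimum gave IFNA2 40 and 31, OSM 355 and 107, both 409 and 105, both against IFNA2 285 and 83, both against OSM 29 and 1, OSM against IFNA2 254 and 104, interaction 1 and 10, above both cytokines 5, below both 0 by limma. Treat against 1.2-fold gave IFNA2 85 and 3, OSM 832 and 416, both 867 and 468, both against IFNA2 544 and 351, both against OSM 40 and 3, OSM against IFNA2 490 and 329, interaction 1 and 8, above both cytokines 11, below both 3. An adjusted p under 0.01 gave IFNA2 226 and 27, OSM 907 lower, both 1006 lower, both against IFNA2 941 lower, both against OSM 21 lower, OSM against IFNA2 749 lower, interaction 2 and 20, above both cytokines 27, below both 11. Without _s_at and _x_at probe sets the counts were IFNA2 559 and 224, OSM 1156 and 937, both 1069 and 1025, both against IFNA2 681 and 871, both against OSM 57 higher, OSM against IFNA2 661 and 704, interaction 6 and 33, above both cytokines 30. Array weights gave IFNA2 3040 and 1887, OSM 2709 lower, both 2655 lower, both against IFNA2 2158 and 2931, both against OSM 1738 and 1906, OSM against IFNA2 1791 and 2328, interaction 2164 and 3430, above both cytokines 412, below both 640. The Alu covariate gave IFNA2 276 and 55, both against OSM 165 and 134, above both cytokines 94, below both 76. The poly-A covariate gave IFNA2 410 and 102, both against OSM 244 and 328, interaction 183 and 539, above both cytokines 131, below both 171. Fits of only the compared arrays gave IFNA2 861 lower, both against OSM 56 and 9, above both cytokines 24, below both 8. A filter at log2 7 gave interaction 20 and 90. The mean of probe sets gave below both 17. A replicate block gave interaction 5 higher. A shift to 1 median gave IFNA2 505 and 433, OSM 1524 and 2034, both 1515 and 2117, interaction 22 and 35, so that more genes fell than rose with OSM and with both. Quantile normalization gave IFNA2 621 and 396, OSM 1716 and 1712, both 1625 and 1923, interaction 20 and 47. More genes also fell than rose with both under array weights (2356 and 2655) and the Alu (1776 and 1852) and poly-A (1790 and 1940) covariates. The fry test called 140 lists, against 84. Leaving out 1 array gave these lowest and highest counts: IFNA2 292 to 1690 and 43 to 939, OSM 1561 to 2171 and 1179 to 1835, both 1535 to 1863 and 1339 to 1782, both against IFNA2 959 to 1299 and 1202 to 1819, both against OSM 77 to 103 and 24 to 78, OSM against IFNA2 922 to 1201 and 975 to 1427, interaction 4 to 836 and 24 to 1491, above both cytokines 32 to 49, below both 16 to 46, lists 73 to 87, and a Pearson r of both changes of 0.439 to 0.547. Directions changed without _s_at and _x_at probe sets for CASP4 in IFNA2 (-0.02), GADD45B in IFNA2 (-0.03), RPS6 in both (0.11), with the most variable probe set for RPS6 in both (0.11), with array weights for COL1A1 in both against OSM (-0.25), ELOVL6 in both against OSM (0.57), IL1R1 in the interaction (0.26), KIF11 in both against OSM (0.51), PIAS1 in both against OSM (0.33), and for the interaction on the linear scale, in intensity, for C1S (582), CFB (135), LBP (417), LCN2 (176), MT1M (3.58), OAS3 (146), SERPINA3 (32.2), UBE2L6 (550). Of the 133 named genes, 14 were not tested with the filter at log2 7 and 43 without _s_at and _x_at probe sets. Replicate numbers did not pair the arrays: same-numbered arrays of different groups correlated from -0.75 to 0.77, 9 of 24 pairs over 0.1, so the replicate block is an alternative only. Signal over background limits the genes under log2 5.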

Other observations

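The regroupings of the arrays below were planned for called genes and lists, and those for separated arrays and the permutation of residuals were chosen after the results were seen; genes of lists that were not called were picked after their values were seen. OSM changed several groups of liver genes in both directions. Of 23 hepatocyte secretory and transcription factor genes 6 rose and 5 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.79; the median was -0.11 and the mean 0.09): the urea cycle enzyme ARG1 rose by 2.88 ± 0.23, and the carrier proteins TTR (-0.7 ± 0.12) and AHSG (-0.6 ± 0.11) fell. Of 20 coagulation genes 11 rose and 4 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.11), with PLG up by 2.16 ± 0.09 and F13B, the B chain of coagulation factor XIII, down (-1.02 ± 0.18). Of 18 matrix and protease genes 9 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.13), with the collagen-binding SPARC up by 1.26 ± 0.12, the collagen crosslinker LOX by 1.1 ± 0.08 and the laminin chain LAMC1 down (-0.81 ± 0.07). Of 13 P450, bile acid and transport genes 3 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.53), with the exporter ABCC3 up by 1.09 ± 0.06 and the sulfotransferase SULT2A1 down (-0.85 ± 0.13). Of 11 gluconeogenesis and fatty acid oxidation genes 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.25), with CPT1A, which admits fatty acids to mitochondria, up by 1.48 ± 0.09. Of 10 fetal liver and progenitor genes SPP1 rose by 3.66 ± 0.12 and SOX4 (-1.22 ± 0.1), ITGA6 (-0.85 ± 0.23) and SOX9 (-0.52 ± 0.08) fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.53; the median was -0.05 and the mean 0.14).

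Of 10 viral sensing genes 6 rose with OSM (7 adjusted over the list alone; camera adjusted p = 0.074), and of 16 hepatitis C virus host factors 4 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.57). Of 21 cholesterol and fatty acid synthesis genes NSDHL rose by 0.38 ± 0.11, and ELOVL6 (-0.85 ± 0.28), SC5D (-0.56 ± 0.18) and IDI1 (-0.37 ± 0.13) fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.82; the median was 0.01 and the mean -0.02); none of the 3 was called without OSM replicate 2 or 3 or untreated replicate 2 or 3 (adjusted p up to 0.084, 0.07 and 0.095). Of 6 fibroblast, stellate and endothelial markers COL1A2 rose by 2.56 ± 0.09 and COL1A1 fell (-0.41 ± 0.14; 1 and 1 adjusted over the list alone; camera adjusted p = 0.64), the last not called without OSM replicate 1 or 2 or untreated replicate 2 or 4 (adjusted p up to 0.093). Of 5 leukocyte markers CD14, which hepatocytes also make, rose by 2.01 ± 0.12 and CD3D by 1.27 ± 0.14 (2 adjusted over the list alone; camera adjusted p = 0.39; the median was -0.11 and the mean 0.53). Of 18 ribosomal genes RPS6 fell (-0.18 ± 0.07; limma called 0 adjusted over the list alone; camera adjusted p = 0.75), not called without any OSM replicate but 4 or any untreated replicate but 1 (adjusted p up to 0.11). When IFNA2 was added to OSM, 4 of 20 coagulation genes fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.00059, and adjusted p = 0.11 with an estimated correlation): F12 (-0.58 ± 0.08), SERPINF2 (-0.52 ± 0.09), KNG1 (-0.5 ± 0.08), PLG (-0.36 ± 0.09) and, upward, TFPI2 (0.54 ± 0.12), the last 2 not called with 1 of 11 and 1 of 8 single arrays left out (adjusted p up to 0.16 and 0.099). CXCL10 (0.57 ± 0.09), CXCL8 (0.46 ± 0.07) and IL15 (0.56 ± 0.13) were the 3 of 17 chemokines that rose (6 adjusted over the list alone; camera adjusted p = 2e-06), IL15 not with 1 of 11 single arrays left out (adjusted p up to 0.14).

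Regrouping the 8 arrays of a comparison in the 34 other ways gave 0 genes called by limma in place of the 3507 for OSM against untreated, the 3492 for the combination against untreated and the 2298 for OSM against IFNA2. That argues against chance there but does not exclude it. With 35 splits the real one ranks first by chance 1 time in 35, and no smaller share could be reached. What it argues against is only that the groups do not differ at all. The 0 is no rate of false calls, since exchanged arrays add the treatment difference to the spread. The 9 lists called for the combination against OSM were the most of the 35 splits as well (highest other 7). That margin is small, and the list counts of the other comparisons were matched or exceeded, so chance is not excluded for these 9. With an estimated correlation 4 of these 9 lists were called, and that was not put to the splits. Beside the signalling and coagulation lists, those lost were the STAT3 pathway, where SOCS2 (0.47 ± 0.1) was the 1 of 20 that rose (2 adjusted over the list alone; camera adjusted p = 0.049, then 0.087), and cytokine receptors and NF-kB, where ICAM1 (0.3 ± 0.07) was the 1 of 17 and of 12 (2 and 2 adjusted over the lists alone; camera adjusted p = 0.0068, then 0.06, and 0.0011, then 0.29). SOCS2 was not called with 1 of 5 single arrays left out (adjusted p up to 0.082), nor ICAM1 with 1 of 12 (up to 0.14). The count of genes with fully separated arrays, called or not, uses no estimate of spread. It too argues against chance for OSM (3162, highest other 1262), the combination against untreated (3362 and 1093) and OSM against IFNA2 (2256 and 1048). It does not for IFNA2 (1834 and 2860) or the combination against IFNA2 (2382 and 2631) or OSM (496 and 2274). The count of called genes does not argue against chance for the 1325 genes of IFNA2 against untreated (highest other 1683), the 2597 of the combination against IFNA2 (2712) or the 142 against OSM (1963). Nor does it for the lists called: 10 for IFNA2 (13), 16 for OSM (18), 17 for the combination against untreated (17), 14 against IFNA2 (16) and 11 for OSM against IFNA2 (14). These highest counts of called genes and lists do not measure chance alone, however: all came from the 16 splits that exchange 1 array and so keep part of the treatment difference. The 18 splits that exchange 2 arrays called at most 1 gene and 3 lists, although there the treatment difference adds to the spread within groups. Other values exclude chance for the antiviral response to IFNA2: MX1 rose by 6.87 ± 0.12 and IFIT1 by 5.97 ± 0.11, and on other arrays they rose by 4.6 ± 0.12 and 5.79 ± 0.11 when IFNA2 was added to OSM.

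For the 47 genes above and the 30 below both cytokines, 100 regroupings of all 16 arrays gave 0 others. This argues only against 4 groups that do not differ at all. For the interaction the arrays without OSM and those with it were regrouped among themselves. That puts the effect of IFNA2 into the spread, so it tests no interaction, and neither the 61 genes (highest other 1371) nor the 7 lists (10; 12 of 100 splits called as many) are judged by it. Permuting the residuals of a fit without an interaction, which keeps both single effects, gave as many genes in 3 of 100 draws, the real one included. This argues against chance for the presence of an interaction but does not exclude it. The test and its bound were set after the results were seen, and the permuted draws with as many genes called 1305 and 2697. Splits and draws that called several times the real count point to a structure of the samples within groups. In the splits with 2712 and 1963 genes IFNA2+OSM replicates 1, 2 and 4 stood apart from replicate 3, which lay at -28.72 on the first axis of within-group variation, against 7.47, 5.55 and 15.7. That axis held 64.9% of the within-group variance, and in the split with 1683 genes IFNA2 replicate 1 (20.07) joined untreated replicates 2, 3 and 4. The labels give no batch to compare this axis with, but it went in part with the array controls, looked at afterwards. IFNA2+OSM replicate 3 had the lowest Alu (13.77) and highest poly-A signal (6.262) of its group. IFNA2 replicate 1 had the highest Alu (14.017) and lowest poly-A signal (5.464) of its group. With OSM, replicate 4 lay highest on the axis (15.71) with less Alu signal (13.913) than replicate 1 (8.3 and 14.117). RNA or labelling differences as the source of the axis were not tested.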
